A study of Mus musculus with 8 samples.

How the data were processed

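Poly-A selected RNA of the mouse hepatoma line Hepa1-6 was sequenced as paired-end libraries, per the labels' protocols, in 4 libraries from cells infected with an adenovirus carrying mouse Dyrk1b (Ad-Dyrk1b) and 4 from cells infected with an adenovirus carrying EGFP (Ad-EGFP). Groups and replicate numbers were taken from the sample titles. The labels do not say that the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

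The authors deposited 1 table of 27876 genes with whole-number counts and FPKM values for each library, per the file headers. The mm10 genome build and edgeR are named in the submitters' processing notes without a role, and the aligner, the counting tool and the annotation are not given in the sources used here. From the values, the counts deposited by the authors were not normalized, since they were whole numbers whose totals differed between libraries. From the values, the FPKM deposited by the authors equalled the count divided by the library total and by a gene length, and for 93.4% of the genes with an annotation that length lay within 1% of the summed length of the distinct annotated exons in GENCODE M21. The table also holds the authors' mean FPKM per group, the log2 ratio of these means, a p-value and an adjusted p-value (q-value), per the file headers. The test behind those p-values is not stated. Gene coordinates are those of the deposited table, and 26298 of the 27817 genes found in GENCODE M21 had identical coordinates there. The handling of strand in counting is not stated, so reads of a gene and of an overlapping gene on the other strand cannot be told apart, and values of near-identical gene copies are uncertain.

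The counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr (minimum count 10, minimum total 15), libraries were scaled with TMM, and a quasi-likelihood F test compared the groups with no other term. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Every adjusted p given for a single gene comes from this edgeR test. Expression is given as CPM on the TMM scale, unless stated otherwise. Totals ranged from 13576077 to 16307084 counts per library. Confidence intervals are at 95%, binomial ones are exact Clopper-Pearson intervals, and a group with 0 counts was set at a floor of 3 counts over its 4 libraries. These intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

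Before the data were examined, 26 gene lists, the main test, the alternatives and the rule for naming genes were fixed. The lists cover gluconeogenesis, glycolysis, glycogen metabolism, insulin signalling, fatty acid and triglyceride synthesis, cholesterol synthesis, fatty acid oxidation, hepatocyte identity, bile acids, proliferation, quiescence and G1 control, hedgehog signalling, the interferon response, NF-kB and acute phase genes, ER stress, p53 targets, oxidative stress defence, Hippo and Wnt targets, extracellular matrix, immediate early genes, DYRK kinases, the clock, hypoxia, mitochondrially encoded genes, markers of other cell types and ribosomal proteins. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists. The named genes are a fixed panel, the 12 genes in each direction with the largest log2 fold change (adjusted p below 0.05, at least 1 CPM in the higher group, no predicted symbol, no overlap between the groups), the 3 in each direction with the smallest p, and up to 2 members of each list in each direction with the smallest p. Where no member of a list passed, the members with the highest expression were to be named, which did not arise. The panel gene Fbp1 was not analysed here, and some genes that the rule names are not reported here.

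The alternatives were a replicate block, each library left out in turn, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) with FPKM of at least 1 in at least 4 libraries, DESeq2 size factors in edgeR, scaling by total count only, no filter, a filter of 1 CPM in 4 libraries, minimum folds of 1.5 and 2, and Dyrk1b left out of the totals. A correction for GC content and length was added after seeing the data.

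The procedures were tested on simulated data with 200 genes changed by known folds. Library sizes were those of the data, and the means were those of the Ad-EGFP libraries. The spread was the edgeR estimate for each gene, and genes removed by the filter were given the largest estimate. In the data, 48.2% of the tested genes passed, so the shares below need not carry over. Of 14346 simulated genes tested, edgeR recovered 18.8% of the genes changed 1.25-fold, 41.7% of those changed 1.5-fold, 78.7% of those changed 2-fold and 95.8% of those changed 4-fold, and 8.2% of its calls were false. DESeq2, used as an alternative, had 28.0% false calls in the same simulation over 27876 genes, which included those given the largest spread. With no gene changed, edgeR called 0 of 14327 genes, and the other tools were not run on that simulation. In a simulation with 1 list raised, camera called that list and 0 of the 25 unchanged lists. The simulated genes were drawn independently, so false list calls among correlated genes could not appear. In the data, the estimated correlation ran from -0.0771 for bile acids to 0.612 for mitochondrially encoded genes.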

Results

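Dyrk1b is a protein kinase of the DYRK family, and the comparison of Ad-Dyrk1b with Ad-EGFP asked which transcripts differ when liver-derived cells carry an excess of it. Hepa1-6 is an established mouse hepatoma line, and the EGFP virus served as the control for infection. Each group had 4 libraries. The Ad-Dyrk1b libraries held 14823835 to 16307084 counts and the Ad-EGFP libraries 13576077 to 15729142. Pairs of libraries of the same group differed by more than counting noise, with a mean chi-square per gene between 7.49 and 19.0. Pairs across the groups gave 64.1 to 76.7. This mean includes Dyrk1b itself, whose large difference raises the values across the groups, and it was not computed without that gene. The first principal component held 58.5% of the variance and separated the groups. On the second component, with 8.69% of the variance, Ad-Dyrk1b replicate 3 stood apart at -29.4, and the other Ad-Dyrk1b libraries lay between 7.72 and 13.1.

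Dyrk1b (ENSMUSG00000002409, mm10 chromosome 7, 28179469 to 28187294) followed the labels in every library. Its counts were 456838, 425949, 453648 and 448928 in the Ad-Dyrk1b libraries and 268, 291, 235 and 272 in the Ad-EGFP libraries. The mean level was 29504.9 ± 1806.4 CPM with Ad-Dyrk1b and 18.0 ± 0.715 CPM with Ad-EGFP (SD, n = 4 each). The log2 fold change was 10.68 (SE 0.08, edgeR adjusted p = 6.09e-14), and a two-sided exact permutation test over the 70 assignments gave p = 0.0286, the smallest it can give. Dyrk1b alone took 2.61% of all counts in Ad-Dyrk1b replicate 2 (95% Clopper-Pearson interval 2.60% to 2.62%) and 3.03% in replicate 4 (3.02% to 3.04%). Reads of the viral and the chromosomal gene are counted together in these values. The related kinase gene Dyrk1a did not pass the test (log2 fold change -0.061, edgeR adjusted p = 0.424), and the neighbouring gene Fbl, named after its values were seen, did not pass either (log2 fold change -0.39, edgeR adjusted p = 0.0729).

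**Figure D1:**
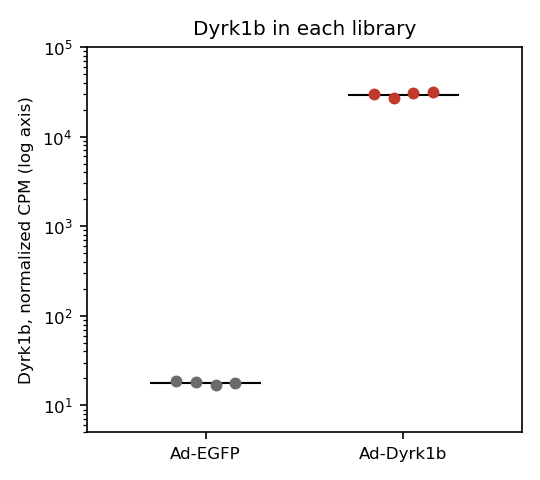
Normalized Dyrk1b level in CPM on a log axis for each of the 8 libraries, with 1 point per library and a line at the group mean. The Ad-Dyrk1b libraries lie near 29504.9 CPM and the Ad-EGFP libraries near 18.0 CPM, with no overlap.

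Beyond Dyrk1b, the change was broad and mostly small. Of 14712 genes tested, 3561 rose and 3523 fell, which is 48.2% of the genes, and 59.5% of these changed by less than 1.5-fold. At least a 2-fold difference was reached by 830 genes that rose and 367 that fell. The groups did not overlap at 6623 genes, and chance gives 2.86% of the tested genes. With scaling by total count only, 2960 genes rose and 4458 fell, so the balance of higher and lower genes depended on the scaling, with 50.3% of the calls higher under TMM. With limma on log2(FPKM + 1), which also differs in the test, the filter and the genes tested, 2293 rose and 3967 fell.

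The largest increases after Dyrk1b were found in genes that lay below 1 CPM with Ad-EGFP. Syk, a cytoplasmic tyrosine kinase, had 104 counts in the Ad-Dyrk1b group and 2 in the Ad-EGFP group, a ratio of 50.8 (95% counting interval 13.7 to 425.3). Nts, the neurotensin precursor, rose by 5.06 on the log2 scale over 5 Ad-EGFP counts, and Ntsr2, a neurotensin receptor, by 3.48 over 14. The chemokine gene Cxcl17 rose by 4.16 over 8 Ad-EGFP counts, Fermt1 by 3.97 over 15 and Ntm by 3.75 over 5. These 5 sizes are imprecise: without Ad-EGFP replicate 2 the log2 fold change was 5.81 for Nts, 4.79 for Fermt1 and 4.51 for Ntm, and without Ad-EGFP replicate 1 it was 5.08 for Cxcl17 and 4.50 for Ntsr2. The phosphodiesterase gene Pde6a rose 15.4-fold over 16 Ad-EGFP counts, Car6 11.5-fold over 8 and Wisp1 11.2-fold over 16. The thyroglobulin gene Tg rose by 3.46 on the log2 scale over 7, so these sizes rest on few counts too. Tat, which encodes the tyrosine aminotransferase of the liver, rose from 0.812 ± 0.181 to 8.74 ± 0.943 CPM (SD, n = 4 each), a 10.7-fold change (log2 fold change 3.42, SE 0.18, edgeR adjusted p = 4.99e-07). The edgeR adjusted p of these genes was at most 0.00126.

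Among the largest decreases, 3 genes had 0 counts in all 4 Ad-Dyrk1b libraries. Prelp, an extracellular matrix proteoglycan gene with 196 counts in the Ad-EGFP group, was at least 66.8-fold lower, the gap junction gene Gjc1 at least 36.8-fold lower and the transcription factor gene Spdef at least 20.8-fold lower, each against 3 counts over the group. Efhd1 had 2 counts against 84 in the Ad-EGFP group, a ratio of 43.0 (95% counting interval 11.5 to 360.6), and Crispld2 had 2 against 77, a ratio of 39.4 (10.5 to 331.0). Both Efhd1 counts came from Ad-Dyrk1b replicate 2, and without that library the Ad-Dyrk1b group had 0 counts and Efhd1 was at least 21.2-fold lower, against 3 counts over the group. The synaptic vesicle gene Svop fell by 4.25 on the log2 scale and the mucin gene Muc2 fell by 3.42. Zdbf2, with 4 Ad-Dyrk1b counts, fell by 3.93, and Dock3, with 7, fell by 3.25, so both sizes are imprecise. Plch2 and Islr2, with 4 Ad-Dyrk1b counts each, had log2 fold changes of -4.64 and -4.56, and Jakmip3, with 6, had one of -3.25. The sizes of Plch2, Islr2 and Jakmip3 are also imprecise: the value was -5.95 for Plch2 without Ad-Dyrk1b replicate 4, and -5.85 for Islr2 and -4.28 for Jakmip3 without Ad-Dyrk1b replicate 1. The edgeR adjusted p of these genes was at most 0.00106.

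The smallest p-values among genes that rose belonged to Dyrk1b, Cxcl15 and Gm5424. Cxcl15 (chromosome 5, 90794534 to 90803067), a chemokine gene, rose from 8.62 ± 0.737 to 81.0 ± 0.756 CPM (SD, n = 4 each, log2 fold change 3.23, SE 0.07, edgeR adjusted p = 2.34e-09). Gm5424 rose by a log2 fold change of 2.26 (edgeR adjusted p = 7.05e-09). The name Gm5424 belongs to a copy of the argininosuccinate synthase gene Ass1, whose own log2 fold change was also 2.26, so reads shared between both make the value of each uncertain. Among genes that fell, Gpnmb (chromosome 6, 49036546 to 49070929), a transmembrane glycoprotein gene, dropped from 428.1 ± 21.7 to 132.3 ± 6.06 CPM (SD, n = 4 each, log2 fold change -1.69, SE 0.05, edgeR adjusted p = 1.92e-08). The complement gene C3 had a log2 fold change of -0.97 (edgeR adjusted p = 1.28e-07) and the translation inhibitor gene Pdcd4 one of -1.96 (edgeR adjusted p = 1.38e-07).

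Glucose production and insulin signalling are the processes named in the title of the study. Pck1 (chromosome 2, 173153048 to 173159273), which encodes the cytosolic enzyme that commits carbon to gluconeogenesis, fell from 1.16 ± 0.242 to 0.115 ± 0.0811 CPM (SD, n = 4 each), with a log2 fold change of -3.23 (SE 0.46, edgeR adjusted p = 2.31e-04). This size is imprecise, since Pck1 had 7 counts with Ad-Dyrk1b and 68 with Ad-EGFP. Its log2 fold change ran from -3.57 to -2.83 when 1 library was left out. Ppargc1a, a coactivator of the gluconeogenesis program, had a log2 fold change of -0.71 (edgeR adjusted p = 0.00156). The mitochondrial enzyme gene Pck2 rose by 0.92 on the log2 scale and the alanine aminotransferase gene Gpt by 1.19, so that 6 of 11 tested gluconeogenesis genes rose and 4 fell, and the list did not stand apart from other genes (camera adjusted p = 0.475). It was 1 of the 19 lists out of 26 that passed fry, here in the upward direction (fry adjusted p = 4.80e-05). The median log2 fold change of its members was 0.27 and the mean only 0.038. G6pc had 0 counts with Ad-Dyrk1b and 8 with Ad-EGFP, too few to be tested. Fgf21, which was also too low to be tested, had 17 counts with Ad-Dyrk1b and 1 with Ad-EGFP, a ratio of 16.6 (95% counting interval 2.60 to 694.6). Without Ad-EGFP replicate 4 the Ad-EGFP group had 0 counts, and Fgf21 was at least 4.13-fold higher. In glycolysis, Aldoc rose by 1.03 and Hk2 by 0.29 on the log2 scale, Pfkl fell by 0.29 and Gpi1 fell by 0.28, and 3 of 20 genes rose and 4 fell (camera adjusted p = 0.475). The call of Gpi1 held only without Ad-Dyrk1b replicate 4 or Ad-EGFP replicate 2 and was lost without each of the other 6 libraries in turn, with edgeR adjusted p up to 0.0834. The pyruvate kinase gene Pklr did not pass (log2 fold change 0.14, edgeR adjusted p = 0.138), except without Ad-Dyrk1b replicate 3 (edgeR adjusted p = 0.0259). Of 13 glycogen genes, 5 rose, among them Ppp1r3c at 0.74 and Gys1 at 0.61, and 4 fell, among them Gyg at -0.77 and Phkb at -0.65 (camera adjusted p = 0.937).

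Irs1, an adaptor between the insulin receptor and its kinases, rose 2.53-fold (log2 fold change 1.34, SE 0.056, edgeR adjusted p = 1.28e-07). Irs2 rose 1.43-fold (edgeR adjusted p = 2.56e-04) and Igfbp1 1.52-fold (edgeR adjusted p = 1.20e-05). Sos1 and Tsc1 had log2 fold changes of -0.42 and -0.39. In all, 10 of 28 insulin signalling genes rose and 7 fell (camera adjusted p = 0.799). Insr (log2 fold change 0.12, edgeR adjusted p = 0.487), Akt2 (0.13, 0.0706), Foxo1 (-0.21, 0.0687) and Rictor (-0.25, 0.0568) did not pass. Without Ad-Dyrk1b replicate 3, Akt2, Foxo1 and Rictor passed at edgeR adjusted p = 0.0316, 0.0355 and 6.78e-04, and without Ad-EGFP replicate 2 Foxo1 passed at 0.0439. With scaling by total count only, Foxo1 and Rictor passed at edgeR adjusted p = 0.0219 and 0.0177, and Rictor also passed with a replicate block. Wbp2, an adaptor protein gene on chromosome 11 (116078573 to 116086995), had 135.2 ± 10.1 CPM with Ad-Dyrk1b and 136.2 ± 2.74 CPM with Ad-EGFP (SD, n = 4 each). Its log2 fold change was -0.010 (SE 0.059, edgeR adjusted p = 0.901).

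**Figure D2:**
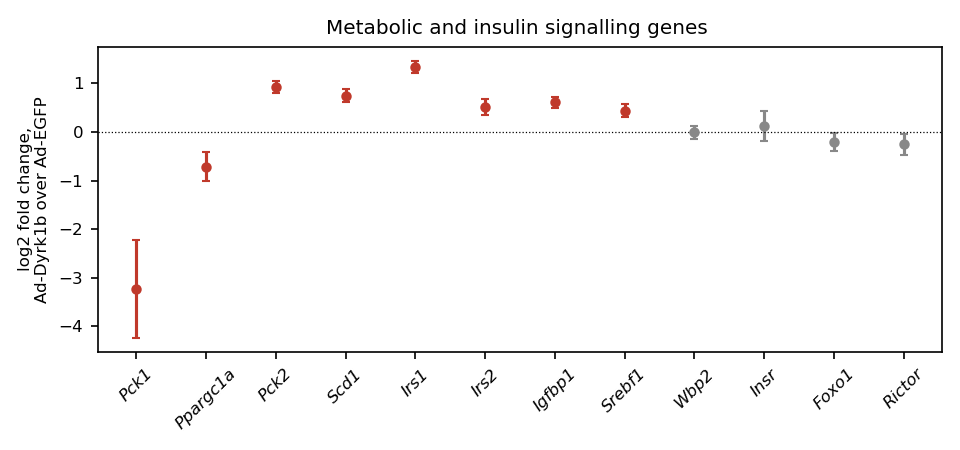
Log2 fold change of Ad-Dyrk1b over Ad-EGFP for 12 metabolic and insulin signalling genes, with points for the estimate, bars for the 95% confidence interval (n = 4 per group) and colour for an edgeR adjusted p below 0.05. Pck1 lies at -3.23 and Irs1 at 1.34, and Wbp2 at -0.010 is grey.

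Lipid genes went both ways. Scd1, the stearoyl-CoA desaturase gene, rose 1.68-fold (508.0 ± 25.9 to 851.3 ± 62.0 CPM, SD, n = 4 each, edgeR adjusted p = 6.29e-06), and Me1 and the transcription factor gene Srebf1 rose by 0.66 and 0.44 on the log2 scale. Acly, which makes cytosolic acetyl-CoA, and Dgat1 had log2 fold changes of -0.40 and -0.49, and Fasn did not pass (0.088, edgeR adjusted p = 0.289). Of 23 genes of fatty acid and triglyceride synthesis, 11 rose and 5 fell (camera adjusted p = 0.111). In cholesterol synthesis and uptake, Acat2 and Hmgcs1 had log2 fold changes of -0.94 and -0.52, and 9 of 26 genes rose and 9 fell (camera adjusted p = 0.937). In fatty acid oxidation and ketogenesis, Cpt1a, the entry step of mitochondrial oxidation, and Hadha had log2 fold changes of -0.95 and -0.86, Acot1 and Bdh1 rose by 0.80 and 0.54, and 5 of 19 genes rose and 9 fell (camera adjusted p = 0.227). The value of Acot1 is uncertain, because its reads can be shared with the near-identical gene Acot2.

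Genes of ER stress and the integrated stress response rose as a group. Of 29 members, 23 rose and 2 fell (camera adjusted p = 5.98e-07, and adjusted p = 0.244 with an estimated correlation). The median member was higher in all 4 Ad-Dyrk1b libraries, by 0.40 to 0.62 on the log2 scale. The serine synthesis gene Psph rose 3.26-fold (48.2 ± 1.40 to 157.1 ± 5.25 CPM, SD, n = 4 each, edgeR adjusted p = 1.33e-08), and the pseudokinase gene Trib3 rose 3.22-fold (edgeR adjusted p = 1.64e-07). Sesn2 and Ddit4 fell, with log2 fold changes of -0.34 and -0.29. Of 25 genes of oxidative stress defence, 10 rose and 3 fell (camera adjusted p = 0.0499, and adjusted p = 0.244 with an estimated correlation), and the call held only without Ad-EGFP replicate 1 (camera adjusted p = 0.0473) and was lost without each of the other 7 libraries in turn, with camera adjusted p up to 0.113. Its members Srxn1 and Hmox1 rose by 0.86 and 0.68, and Txn1 and Sod1 had log2 fold changes of -0.44 and -0.39.

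Immediate early and MAPK feedback genes were higher as a group, with 18 of 27 that rose and 3 that fell (camera adjusted p = 0.00263, and adjusted p = 0.244 with an estimated correlation). Dusp1, a phosphatase gene of MAPK feedback, rose 3.01-fold (edgeR adjusted p = 2.18e-07) and the transcription factor gene Klf6 rose 1.66-fold, while the phosphatase genes Dusp6 and Dusp5 fell by 0.76 and fell by 0.84 on the log2 scale. NF-kB and acute phase genes were lower as a group, with 1 of 19 that rose and 12 that fell (camera adjusted p = 0.00263, and adjusted p = 0.244 with an estimated correlation). The adhesion molecule gene Vcam1 dropped from 45.6 ± 3.61 to 14.5 ± 1.31 CPM (SD, n = 4 each, log2 fold change -1.65, edgeR adjusted p = 6.13e-07) and Nfkbia, the inhibitor of NF-kB, had a log2 fold change of -0.85, whereas Icam1 rose by 0.72. Markers of other cell types were higher as a group, with 8 of 10 that rose and 1 that fell (camera adjusted p = 0.0141, and adjusted p = 0.244 with an estimated correlation). The epithelial genes Epcam and Krt7 rose by 0.95 and 0.98 on the log2 scale, and the macrophage marker Cd68 had a log2 fold change of -1.35. The median of these markers was 0.83 to 0.99 higher in the Ad-Dyrk1b libraries. The stress, immediate early and NF-kB lists differed between the same groups, so this overlap shows no link between the lists, and none was tested. Ribosomal protein genes were lower as a group, with 1 of 73 that rose and 21 that fell (camera adjusted p = 0.0141, and adjusted p = 0.813 with an estimated correlation), and this list did not pass fry (adjusted p = 0.165). Rpl7a and Rpl30 had log2 fold changes of -0.42 and -0.29, and Rpl15 rose by 1.39, though reads shared with pseudogenes make the values of ribosomal protein genes uncertain. The median ribosomal protein gene lay between -0.34 and 0.03 across the Ad-Dyrk1b libraries, and the list's adjusted p reached 0.201 without Ad-Dyrk1b replicate 3.

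**Figure D3:**
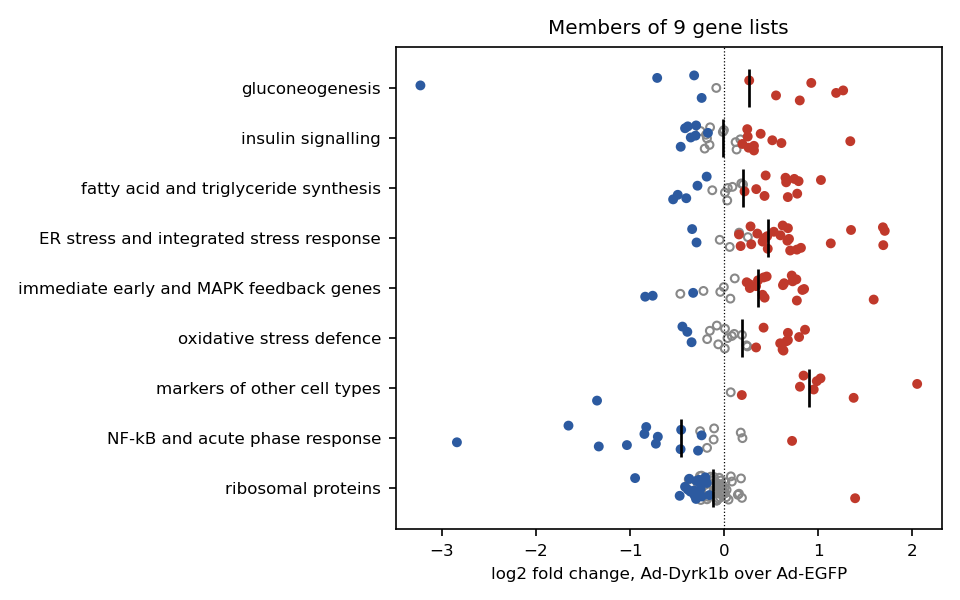
Log2 fold change of each tested member of 9 gene lists, Ad-Dyrk1b over Ad-EGFP, with filled points for an edgeR adjusted p below 0.05 (red higher, blue lower), open points for the others and a black line at the median. The median of the 29 ER stress genes is 0.46 and that of the 19 NF-kB and acute phase genes is -0.46.

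The other lists did not pass the camera test. In cell proliferation, Ccne1 rose 2.29-fold and Aurka 1.67-fold, Foxm1 and Mcm7 had log2 fold changes of -0.71 and -0.37, and 10 of 35 genes rose and 5 fell (adjusted p = 0.543). Among quiescence and G1 genes, Cdkn2b rose by 0.34 and Cdkn1a by 0.28, the retinoblastoma genes Rb1 and Rbl1 had log2 fold changes of -0.65 and -0.53, and 5 of 20 rose and 6 fell (adjusted p = 0.475). Ccnd1 rose by 0.14 (edgeR adjusted p = 0.0124), a call lost with scaling by total count only (edgeR adjusted p = 0.164) and without Ad-EGFP replicate 3 (0.0613) or 4 (0.0507). Among hedgehog genes, Ihh rose 5.63-fold and Gli1 2.59-fold, Smo and Sufu had log2 fold changes of -0.38 and -0.30, and 4 of 9 rose and 4 fell (adjusted p = 0.786). Among p53 targets, Plk3 and Gadd45a rose by 0.94 and 0.92, Fas and Ccng1 had log2 fold changes of -1.47 and -0.86, and 7 of 24 rose and 12 fell (adjusted p = 0.229). In the interferon response, Oasl1 and Usp18 rose by 0.97 and 0.28, Ifih1 had a log2 fold change of -1.19, and 8 of 24 rose and 5 fell (adjusted p = 0.799). Among Hippo and Wnt targets, Notum rose 4.30-fold and Nkd1 2.48-fold, Cyr61 and Ajuba had log2 fold changes of -0.67 and -0.42, and 8 of 28 rose and 7 fell (adjusted p = 0.895).

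Among hepatocyte identity genes, the oncofetal gene Afp rose by 0.62 and Tat as above, Apoe and Fgb had log2 fold changes of -0.82 and -0.53, and 8 of 19 rose and 5 fell (camera adjusted p = 0.475). Baat and Abcc3 rose by 1.04 and 0.30 and Cyp7b1 fell by 0.44 among bile acid genes, of which 3 of 6 rose and 1 fell (adjusted p = 0.354). The call of Cyp7b1 was lost without Ad-Dyrk1b replicate 4 and without Ad-EGFP replicate 1, 2 or 4, with edgeR adjusted p up to 0.0909. Among matrix genes, Mmp14 and Snai1 rose by 0.89 and 0.73, Spp1 and Col6a1 had log2 fold changes of -0.96 and -0.88, and 10 of 21 rose and 3 fell (adjusted p = 0.303). Among DYRK and related kinases and partners, which include Dyrk1b, Clk3 rose by 0.58, Clk2 and the DYRK-binding protein gene Dcaf7 had log2 fold changes of -0.56 and -0.48, and 4 of 17 rose and 5 fell (adjusted p = 0.988). Among clock genes, Cry1 rose 2.44-fold and Cry2 1.72-fold, Nr1d2 and Clock had log2 fold changes of -0.31 and -0.34, and 8 of 16 rose and 3 fell (adjusted p = 0.229). The call of Clock held only without Ad-Dyrk1b replicate 1 or Ad-EGFP replicate 3 and was lost without each of the other 6 libraries in turn, with edgeR adjusted p up to 0.0932. Among hypoxia genes, Ndrg1 rose 2.04-fold and P4ha1 1.59-fold, Slc2a3 and Ankrd37 had log2 fold changes of -2.03 and -0.77, and 8 of 17 rose and 3 fell (adjusted p = 0.229). Among mitochondrially encoded genes, mt-Nd5 and mt-Cytb rose by 0.42 and 0.33, mt-Atp8, which overlaps mt-Atp6 and is therefore uncertain, fell by 0.32, and 5 of 13 rose and 1 fell (adjusted p = 0.475).

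The counts adjusted over the list alone equalled those over all genes except in 6 lists. Adjusted over the list alone, 3 glycolysis genes rose and 1 fell, 10 insulin signalling genes rose and 8 fell, 5 fatty acid oxidation genes rose and 10 fell, 8 interferon genes rose and 6 fell, 2 NF-kB genes rose and 13 fell, and 1 ribosomal protein gene rose and 18 fell. With fry, which tests whether the members of a list move on balance one way, 19 of 26 lists passed, and its test for change in either direction passed in all 26. The median and the camera direction differed in sign for insulin signalling, for Hippo and Wnt targets and for cholesterol synthesis, and the median and the mean differed in sign for these 3 lists and for glycogen metabolism.

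The authors' deposited table marks 418 genes as higher and 299 as lower, all with a q-value below 0.05, at least a 2-fold ratio of mean FPKM and a mean of at least 1 FPKM in the higher group. Of these genes in the authors' deposited table, 376 also rose and 278 also fell in the edgeR test. In the authors' deposited table, Dyrk1b has a log2 ratio of 10.61 and Wbp2 one of -0.08 with a q-value of 0.909. Pck1 has a log2 ratio of -3.40 in the authors' deposited table, and its mean of 0.211 FPKM with Ad-EGFP lies below that level of 1 FPKM.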

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

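In 288 sets of 4 library values, 23 had 1 library far from the other 3, where chance alone gives about 14.4. The test of other splits of the libraries was chosen before its result was seen.

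In the Ad-EGFP group, replicate 1 stood apart from the others for Insr (44.9 CPM), Pdcd4 (64.3), Hk2 (264.2) and Sesn2 (79.1), replicate 2 for Ajuba (122.4), Snai1 (19.9) and Clk2 (49.9), replicate 3 for Pck1 (1.52), Dock3 (1.59) and Gm5424 (17.9), and replicate 4 for G6pc (0.331) and Fgf21 (0.0662). In the Ad-Dyrk1b group, replicate 1 stood apart for Dyrk1a (38.6 CPM) and Sufu (56.0), replicate 2 for Efhd1 (0.126), replicate 3 for Pklr (24.5), Dgat1 (14.2), Ifih1 (13.3), Col6a1 (18.8) and mt-Nd5 (2055.1), and replicate 4 for Gpi1 (650.8), Tsc1 (31.4) and Cyp7b1 (4.64). The most values, 5, came from Ad-Dyrk1b replicate 3.

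Other splits of the libraries were tested for the number of changed genes. The real split gave 7084 genes, 1 of the 35 splits of the 8 libraries into 4 and 4 gave as many, and the highest of the other splits gave 3. That 1 is the real split itself, so the share is the smallest this test can give. Every other split mixes libraries of both groups, so the group difference widens the spread and lowers the calls. The test therefore cannot exclude grouping by chance.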

How the results depend on the processing

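The correction for GC content and length was chosen after seeing the data. The number of changed genes stayed within 1.5 times 7084 under all alternatives except a minimum fold, and 6412 to 7430 genes passed when 1 library was left out. The Dyrk1b log2 fold change stayed between 10.61 and 10.72 in all of its alternatives. Requiring a 1.5-fold change left 2869 genes, 1665 higher and 1204 lower, and requiring a 2-fold change left 1197, 830 higher and 367 lower, which follows from 59.5% of the changes being smaller than 1.5-fold. With limma on log2(FPKM + 1), 2293 genes were higher, in place of 3561. The FPKM are scaled by the library total, and edgeR with scaling by total count only also gave fewer higher genes, 2960. How much the scaling, the test and the filter each contributed was not tested. The correction for GC content and length gave 7540 genes, and the camera adjusted p of oxidative stress defence was then 0.102. The number of lists that passed was 6 with camera, 0 with an estimated correlation, 19 with fry and 4 to 6 when 1 library was left out. The labels do not say whether replicate numbers pair the samples. Deviations of same-numbered libraries correlated at only 0.0585 to 0.0738, so they were not treated as pairs, although each sample correlated best with its own number, a hint from the data. With a replicate block, 6987 genes and 5 lists passed, Rictor passed (edgeR adjusted p = 0.0323), Cyp7b1 (0.0735) and oxidative stress defence (camera adjusted p = 0.0728) did not, and no other call on a named gene or list changed. Of 136 named genes other than Dyrk1b, 126 kept their direction and side of the threshold in all alternatives run for them. When 1 library was left out, the sign turned, with no call on either side, for Wbp2 (-0.054 to 0.033, turned without Ad-Dyrk1b replicate 3) and Insr (-0.025 to 0.17, turned without Ad-EGFP replicate 1). The camera direction turned in the same way for glycogen metabolism without Ad-Dyrk1b replicate 1 and cholesterol synthesis without Ad-Dyrk1b replicate 2 (adjusted p 0.796 to 0.990 for both), and for the DYRK list without Ad-Dyrk1b replicate 3 or 4 or Ad-EGFP replicate 1 or 2 (0.899 to 0.984). Without a filter it turned for insulin signalling (0.930), Hippo and Wnt targets (0.945) and the DYRK list (0.853). The cause of these turns was not tested. The alternatives planned for a table of FPKM alone (pseudocounts, filters and scaling) or of transcripts were not run, because the table held counts per gene. Depth limits the genes with few counts, such as G6pc and Fgf21.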

Other observations

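The gene sets and patterns below were chosen after seeing the data, and of the tests of explanations, the test of genomic DNA was chosen only after its result was seen. Among 294 KEGG terms of the deposited table with at least 10 tested genes, 17 passed with camera at the preset correlation and 0 with an estimated correlation. Amino acid synthesis was higher, with 26 of 58 genes that rose and 8 that fell (camera adjusted p = 0.0097, and adjusted p = 0.450 with an estimated correlation), and its median was higher in all 4 Ad-Dyrk1b libraries. Named after their values were seen, the transsulfuration genes Cth and Cbs rose by 2.41 and 1.92 on the log2 scale, the proline synthesis gene Pycr1 by 2.41 and the urea cycle gene Ass1, which can share reads with Gm5424, by 2.26. In pancreatic secretion, a term with 25 of 49 genes that rose and 9 that fell (camera adjusted p = 0.025, and adjusted p = 0.450 with an estimated correlation), the calcium-activated chloride channel regulator genes Clca3a1, Clca3a2 and Clca3b rose by 3.32, 2.97 and 2.03, and reads shared among these neighbours make each value uncertain.

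Spliceosome genes were lower, with 54 of 118 that fell and 10 that rose (camera adjusted p = 0.00507, and adjusted p = 0.450 with an estimated correlation), and so were genes of oxidative phosphorylation, with 55 of 112 that fell and 13 that rose (camera adjusted p = 0.0097, and adjusted p = 0.583 with an estimated correlation). The helicase genes Dhx16 and Aqr had log2 fold changes of -0.88 and -0.97, and the complex I gene Ndufb7 one of -1.17. Both sets had a lower median in all 4 Ad-Dyrk1b libraries. After each library was corrected for GC content and transcript length, the larger camera adjusted p of both sets was 9.74e-04, which argues against these properties as the whole cause. A change in these sets with Dyrk1b may be followed up as a hypothesis, although other biases were not tested.

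Antisense and long intergenic RNA genes were mostly called higher, 246 against 51 that were lower, or 82.8% of the calls, and the highest share in 1000 draws of protein-coding genes matched on expression was 72.1%, which argues against low expression as the whole cause. The median share in these draws was 63%, against 49.1% for all protein-coding genes, so part of the excess went with low expression. Other classes went both ways: 55 processed transcripts were higher and 13 lower, against 0 and 11 snoRNA genes (median log2 fold change -0.35), 4 and 5 sense intronic genes (-0.26) and 98 and 207 processed pseudogenes (-0.12), whose reads can come from other gene copies. The 282 protein-coding genes that overlap antisense genes had a median log2 fold change of 0.0353 (95% bootstrap interval -0.032 to 0.12), against 0.35 for the antisense genes, which argues against reads from the other strand as the whole cause. Genomic DNA in the Ad-Dyrk1b libraries cannot be told apart from a change in transcription. Olfactory, vomeronasal, trace amine and taste receptor, beta-defensin and keratin-associated protein genes were taken as silent in liver cells. Their pooled level was 66.0 ± 5.19 CPM with Ad-Dyrk1b and 44.9 ± 2.97 CPM with Ad-EGFP (SD, n = 4 each). The 16 log2 differences between libraries ran from 0.36 to 0.84. All levels and differences of these families were scaled by total count only. The 0.38 median of the noncoding genes is on the TMM scale, so it cannot be placed directly within that range. TMM factors were 0.971 to 0.982 with Ad-Dyrk1b and 1.016 to 1.033 with Ad-EGFP, so TMM scaling would raise each difference of these families. Of the counts of these families, 49.7% lay in 10 of the 221 genes, some of which differed strongly, such as Olfr1029 (4.35 against 0.546 CPM) and Vmn1r40 (4.86 against 0.976 CPM), and without these 10 the levels were 30.8 ± 2.78 and 25.2 ± 3.19 CPM, with a mean log2 difference of 0.29 (0.021 to 0.72) in place of 0.55.

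Protein-coding genes with 23 or more exons were called lower in 39.5% of cases and higher in 20.1%, and those with 1 to 4 exons in 20.9% and 25.5%. Across 12180 genes, which are not independent replicates, the Spearman rho of exon number and log2 fold change was -0.0736, and it averaged -0.0689 within deciles of GC content and -0.0982 within deciles of expression, which argues against either as the whole cause, and -0.0409 within deciles of transcript length. A correlation of rank residuals after a smooth fit on all 3 together was -0.0643, which does not isolate length, so length stays open. The trend was not shared by all libraries: against the mean of the Ad-EGFP libraries, rho was -0.121, -0.146, 0.0465 and -0.0695 in Ad-Dyrk1b replicates 1 to 4, and single Ad-EGFP libraries set against the other 3 gave -0.0827 to 0.0891. Differences between libraries of the same group may therefore be as large as the trend.

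With Ad-Dyrk1b, 4 genes had 0 counts in all 4 libraries while each Ad-EGFP library held at least 10, namely Spdef, Gjc1, Prelp and the long intergenic RNA gene Gm839, and 0 genes showed the opposite. Chosen after its values were seen, a stretch of chromosome 5 held 16 tested genes, of which 10 rose, 3 fell and 3 did not pass. It held Alb, Afp, Afm, Rassf6, Ppbp, Cxcl15 and Areg, which rose by 0.51, 0.62, 2.81, 0.50, 0.87, 3.23 and 0.83 on the log2 scale, among Cxcl5, Cxcl1 and Cxcl2, which had log2 fold changes of -0.73, -1.33 and -1.03, and Cxcl3, Mthfd2l and Btc did not pass (edgeR adjusted p = 0.155, 0.742 and 0.715). The number of genes with at least 1 count was 22733 ± 101.6 with Ad-Dyrk1b and 22126.8 ± 140.6 with Ad-EGFP (SD, n = 4 each, two-sided exact permutation test p = 0.0286, the smallest it can give). Depth differed too, but Ad-Dyrk1b replicates 1, 3 and 4, with 14823835 to 15722783 counts, each had more such genes (22615 to 22847) than the deeper Ad-EGFP replicate 2 (15729142 counts, 22321 genes).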
